A study of Homo sapiens with 12 samples.

How the data were processed

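RNA of HepG2C3A cells from 12 samples was measured on Affymetrix Human Gene 1.0 ST arrays, with 3 arrays in each of 4 groups: Petri control, Petri treated, microsystem control and microsystem treated. Per the labels, cells were cultured for 96 h and treated cells were exposed to acetaminophen for 72 h. The deposited values are log2 intensities per probe set, which the authors made by robust multi-array average in Affymetrix Expression Console, per the submitters' processing notes. The versions of these programs, the acetaminophen dose and a genome build are not given in the sources used here, so no positions are printed. The deposited values were used as they are, without new normalization. The number of arrays limits the precision.

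The deposited values covered 32321 probe sets. Gene symbols came from the array's probe annotation, in which 19158 probe sets had 1 symbol, 1388 had several and 11775 had none here. Probe sets with 1 symbol covered 18404 genes, of which 637 had more than 1 probe set, and the probe set with the highest mean over the 12 arrays stood for the gene. A gene was kept when at least 3 arrays exceeded that array's 40th percentile of all probe sets, which kept 13199 genes and removed 5205.

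A linear model with 1 coefficient per group was fitted to all 12 arrays in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation, leaving 8 residual and 5.35 prior degrees of freedom. The contrasts were treatment in Petri dishes, treatment in the microsystem, culture in controls (microsystem minus Petri), culture in treated cells, and the difference of treatment effects (microsystem minus Petri). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 13199 genes, and genes with adjusted p under 0.05 are said to have risen or fallen. SE values are those of the moderated fit. A total of 34 gene lists from general knowledge, with 814 symbols of which 654 were tested, were compared with other genes by camera with the inter-gene correlation preset at 0.01, adjusted over the 34 lists within a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were the alternatives. Adjusted p-values of lists are those of camera, and those of genes are those of limma. Other tools were data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.

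The groups, tests, filters, lists, alternatives and the rule for naming genes were fixed before the data were examined. Per comparison the rule took, among genes past the threshold whose groups did not overlap, the 8 largest rises and 8 largest falls (4 and 4 for culture in treated cells), and for the difference of treatment effects every gene past the threshold up to these numbers. For each list that passed, it took up to 4 members past the threshold with the largest difference or, where none passed, the member with the smallest adjusted p, of which the text prints some. ALB, AFP, CYP1A1, CYP2E1, CYP3A4, HMOX1, GCLM, CDKN1A and MKI67 were named in both treatment effects and in culture in controls whatever their values. The rule calls genes of the near-identical families UGT1A, SULT1A, MT1, GSTA, HSPA1A/B, CYP3A and HBA uncertain. Histone genes, ORM1, ACOT1 and UGT2B7 are outside it and are called uncertain for the same reason.

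The alternatives were a replicate block, only the arrays compared, quantile normalization, array medians set equal, no filter, a 60th percentile filter, the mean of a gene's probe sets, every probe set by itself, an intensity trend, array weights, a minimum of 1.5-fold, and leaving out each array. A replicate block within each culture, and leaving out both microsystem arrays numbered 3, were added after the values were seen. To check whether replicate numbers pair the arrays, deviations from the group mean were correlated across genes between same-numbered arrays. For treatment in Petri dishes r was 0.48, 0.19 and 0.31, all above 0.1. For treatment in the microsystem r was 0.11, 0.07 and 0.60, for culture in controls 0.18, -0.03 and 0.13, and for culture in treated cells 0.14, -0.14 and 0.13. The procedure was tested on simulated data with 50 changed genes at each fold among 13199. Of those changed 1.5-fold it recovered 70% and 78% for the treatment effects in Petri dishes and the microsystem, 80% and 74% for the culture effects in controls and treated cells and 42% for the difference, and of those changed 2-fold 98%, 92%, 96%, 94% and 84%. It called 8, 11, 7, 6 and 3 unchanged genes. The simulated noise was drawn independently for each gene and array, without the shared deviations of same-numbered arrays, so these rates may not carry over.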

Results

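HepG2C3A is a human cell line derived from a liver tumour and kept for its hepatocyte-like functions, and acetaminophen is an analgesic whose metabolism in the liver yields a reactive quinone imine. Messenger RNA of these cells was measured on 12 Affymetrix Human Gene 1.0 ST arrays. Cells were grown for 96 h either in Petri dishes or in a culture microsystem, which the labels do not describe further, and were left untreated or exposed to acetaminophen for 72 h. The dose is not given in the sources used here. This made 4 groups of 3 arrays each. The array medians of the deposited log2 values lay between 5.556 and 5.629 over 32321 probe sets, and 13199 genes passed the filter on dim probe sets. Within a group, pairs of arrays correlated across probe sets with r between 0.991 and 0.995, and between groups with r between 0.976 and 0.993. No array was a copy of another. The first principal component held 63.7% of the variance and parted the cultures. The second held 14.4% and parted treated from control arrays. The third held 6.77% and set both microsystem arrays numbered 3 apart, at scores of -17.2 and -13.9. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision, and an exact permutation test of 3 arrays against 3 could not go below p = 0.1.

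**Figure D1:**
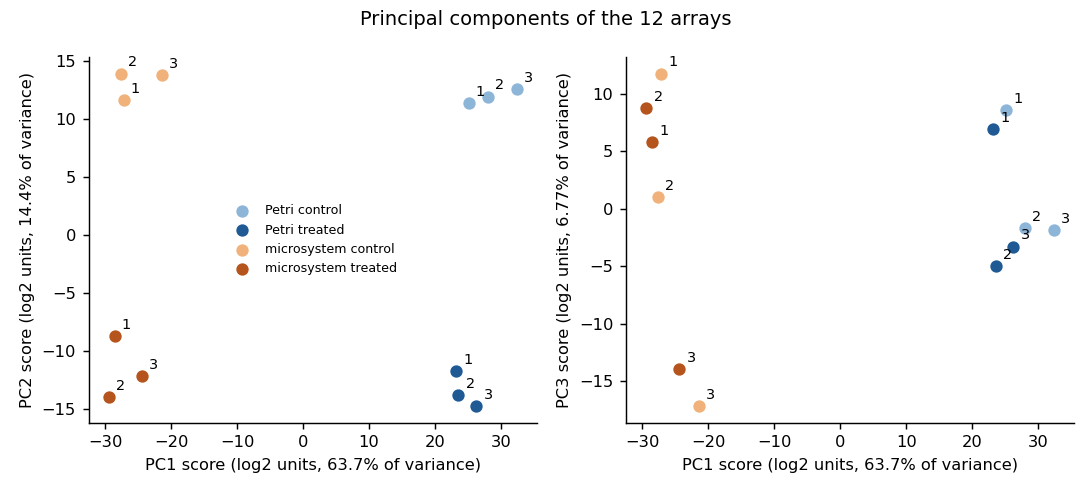
Scores of the 12 arrays on the first 3 principal components of the genes tested, in log2 units, with 1 point per array and its replicate number beside it. The first component (63.7% of the variance) separates Petri from microsystem arrays, the second (14.4%) separates treated from control arrays, and the third (6.77%) sets the microsystem arrays numbered 3 at -17.2 and -13.9.

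The first comparison asked what acetaminophen changed in Petri dishes. The lists of p53 target, DNA replication and mitosis genes shifted up in treated cells. Of these calls, that of p53 targets alone held with an estimated correlation. The largest rise was that of CEL (probe set 8158976), which encodes carboxyl ester lipase, from a log2 value of 5.86 ± 0.10 to 8.27 ± 0.10 (SD, n = 3), a 5.33-fold increase (log2 difference 2.41 ± 0.13 SE, adjusted p = 4.05e-07). TP53I3 (probe set 8050702), a quinone oxidoreductase gene transcribed under p53, rose by 1.87 ± 0.10, and E2F7, a repressor of cell cycle genes, by 1.79 ± 0.10 (adjusted p = 4.05e-07 for both). The cystine importer gene SLC7A11 fell by 1.27 ± 0.25 (adjusted p = 0.00539), while albumin (ALB) and alpha-fetoprotein (AFP) differed by 0.01 ± 0.08 and -0.00 ± 0.13 (adjusted p = 0.958 and 0.994). In all, 1106 genes rose and 261 fell in Petri dishes, and of the 392 that changed by at least 1.5-fold, 363 rose. The share that rose was 80.9%, and 90.7% with array medians set equal (1487 rose and 153 fell). With array weights 2424 rose and 1178 fell. The other genes with the largest rises were PSTPIP2 (1.80 ± 0.14, from a control mean under the 40th percentile of its arrays), the mucin gene MUC13 (1.62 ± 0.19), the myo-inositol transporter gene SLC5A3 (1.61 ± 0.40), the heparan sulfate sulfatase gene SULF2 (1.61 ± 0.13) and the diacylglycerol kinase gene DGKA (1.58 ± 0.13). The largest falls besides SLC7A11 were those of the histone genes H2BC14 (-1.35 ± 0.29) and H2BC3 (-1.03 ± 0.23), which belong to a family of near-identical copies and are uncertain for that reason. Others were those of the tetraspanin gene TSPAN8 (-1.22 ± 0.21), of INHBE (-1.04 ± 0.19), of the osteopontin gene SPP1 (-0.91 ± 0.20), of ORM1 (-0.91 ± 0.24), which encodes a plasma glycoprotein and is uncertain because of its near-identical relative ORM2, and of AGXT (-0.84 ± 0.19), a glyoxylate-detoxifying enzyme of hepatocytes. For every gene named here as changed in Petri dishes, the 3 treated values lay entirely above or below the 3 control values. The naming rule required this of the largest rises and falls, so it is no result for them. Of all genes tested, 34.5% had such a separation, against 10% by chance.

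Of 27 p53 target genes tested, 21 rose in Petri dishes, 0 fell and 6 did not pass, and 24 rose when adjusted over the list alone. Beside TP53I3, the stress-induced regulator TP53INP1 rose by 1.40 ± 0.16, the damage recognition gene DDB2 by 1.18 ± 0.08 and the translesion polymerase gene POLH by 1.07 ± 0.08. The list differed from other genes (camera, adjusted p = 4.23e-21), also with an estimated correlation (adjusted p = 0.028). CDKN1A, the cell cycle inhibitor induced by p53, rose by 0.67 ± 0.10 (adjusted p = 0.00146). Of 40 DNA replication genes, 31 rose, 0 fell and 9 did not pass, and 39 rose when adjusted over the list alone. The origin licensing gene CDC6 rose by 1.33 ± 0.19, the thymidine kinase gene TK1 by 1.24 ± 0.13, the polymerase alpha subunit gene POLA2 by 1.15 ± 0.12 and DTL by 1.06 ± 0.15. This list passed at adjusted p = 2.4e-23, and its call was lost at an adjusted p = 0.436 with an estimated correlation. Of 36 mitosis genes, 17 rose, 0 fell and 19 did not pass, and 31 rose when adjusted over the list alone. They included the cytokinesis genes ANLN (0.89 ± 0.13) and CEP55 (0.77 ± 0.10), the spindle gene ASPM (0.85 ± 0.14) and the checkpoint kinase gene TTK (0.74 ± 0.15), with the proliferation marker MKI67 at 0.57 ± 0.11 (adjusted p = 0.00605). The mitosis list passed at adjusted p = 2.05e-14, against an adjusted p = 0.713 with an estimated correlation.

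Smaller shifts went down in Petri dishes, and none of these list calls held with an estimated correlation. Of 18 cholesterol synthesis genes, 0 rose, 4 fell and 14 did not pass, and 6 fell when adjusted over the list alone. MSMO1, a sterol demethylation enzyme, fell by 0.50 ± 0.08 (adjusted p = 0.00172), HMGCS1, the first committed enzyme of the mevalonate pathway, by 0.47 ± 0.11, DHCR7 by 0.32 ± 0.09, and CYP51A1 by 0.33 ± 0.08, although another probe set of CYP51A1 gave 0.64. As a list, they passed at adjusted p = 0.00631 (adjusted p = 0.845 with an estimated correlation), and without Petri control 1 the call was lost (adjusted p = 0.0941) and the mean went from -0.145 to -0.081. Of 36 plasma protein genes, 3 fell, 0 rose and 33 did not pass, and 0 passed when adjusted over the list alone. They were APOH (-0.49 ± 0.13), VTN (-0.39 ± 0.11) and FETUB (-0.30 ± 0.08). With camera, the list passed at adjusted p = 0.0117 (adjusted p = 0.845 with an estimated correlation, 0.0546 after quantile normalization and 0.239 without Petri control 1, where the mean went from -0.125 to -0.038). The 28 ribosomal protein genes held no member that passed, over all genes or when adjusted over the list alone. RPL22 came nearest at -0.24 ± 0.09 (adjusted p = 0.106). Tested together as a list, these genes passed at adjusted p = 0.0219 (adjusted p = 0.845 with an estimated correlation, 0.175 after quantile normalization and 0.0623 without Petri control 3). Of 29 genes of the ATF4 amino acid response, 2 fell, 0 rose and 27 did not pass, with the same 2 counted when adjusted over the list alone. They were SLC7A11 and the cystathionine gamma-lyase gene CTH (-0.71 ± 0.16). Set against other genes, the list passed at adjusted p = 0.0415 (adjusted p = 0.845 with an estimated correlation). That call was lost without Petri control 2, Petri control 3 or Petri treated 1, with adjusted p from 0.0566 to 0.529, and without both microsystem arrays numbered 3 (adjusted p = 0.0504). The list mean of -0.14 was -0.02 without Petri control 2, -0.07 without Petri treated 1 and -0.27 without Petri control 1. Of 14 drug transporter genes, 1 fell, 0 rose and 13 did not pass, with 1 also when adjusted over the list alone. It was SLC22A9 (-0.42 ± 0.11). This list passed at adjusted p = 0.0421 (adjusted p = 0.436 with an estimated correlation) but lost the call without any of 6 single arrays, with adjusted p from 0.0513 to 0.15.

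Among the genes fixed for report whatever their values, the cytochrome gene CYP1A1 rose in Petri dishes by 0.70 ± 0.14 (adjusted p = 0.00527). CYP2E1, a main activator of acetaminophen, fell by 0.29 ± 0.08 (adjusted p = 0.0378), to a mean under the 40th percentile of its arrays, and the heme oxygenase gene HMOX1 by 0.42 ± 0.12 (adjusted p = 0.033). CYP3A4, whose near-identical relatives make its value uncertain, differed by 0.51 ± 0.19 (adjusted p = 0.103). Its means in Petri dishes, 2.89 and 3.39, lay under the 25th percentile of their arrays, so these values are not shown to be above background. The other genes that did not pass included GCLM, a subunit of the enzyme that limits glutathione synthesis, at 0.21 ± 0.12 (adjusted p = 0.303). With the replicate block within each culture, CYP3A4 passed (adjusted p = 0.00628, range over its alternatives 0.00628 to 0.306) and 2180 genes passed in place of 1367, a fit run because same-numbered Petri arrays deviated together. Without Petri control 2 or 3 or Petri treated 2 or 3, 771, 844, 701 and 730 genes passed. The description of Petri treated replicate 3 carries an asterisk that the labels do not explain. Of the 41 genes named by the fixed rule that passed in Petri dishes, 15 lost the call without some single array, with SLC5A3 (highest adjusted p = 0.08), H2BC3 (0.0568), SPP1 (0.0625), ORM1 (0.103), AGXT (0.061), HMGCS1 (0.0573), DHCR7 (0.129), CYP51A1 (0.0563), APOH (0.111), VTN (0.165), FETUB (0.132), CTH (0.0616), SLC22A9 (0.114), CYP2E1 (0.145) and HMOX1 (0.111).

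The second comparison asked the same of cells in the microsystem. The lists of mitosis, p53 target and DNA replication genes shifted up there too, and that of ribosomal proteins shifted down. None of these calls held with an estimated correlation. The largest rise was that of CYP24A1 (probe set 8067140), the enzyme that inactivates vitamin D, from 7.11 ± 0.74 to 8.89 ± 0.49 (SD, n = 3), by 1.78 ± 0.34 SE (adjusted p = 0.0067). CPB2 (probe set 7971444), which encodes a carboxypeptidase of plasma that slows clot lysis, fell the most, by 1.32 ± 0.17 (adjusted p = 0.000778). ALB and AFP differed by -0.04 ± 0.08 and -0.18 ± 0.13 (adjusted p = 0.788 and 0.409). In all, 843 genes rose and 353 fell in the microsystem, and of the 310 that changed by at least 1.5-fold, 260 rose. The share that rose was 70.5%. Under alternatives it was 64.3% with array weights, 68.4% after quantile normalization, 81.6% with array medians set equal and 84.1% with only the arrays compared. Large rises were also those of the long noncoding RNA UCA1 (1.52 ± 0.33), CYP3A43 (1.44 ± 0.15, uncertain because of its near-identical relatives), both with control means under the 40th percentile of their arrays, the pseudogene FBXL21P (1.43 ± 0.17), the cathepsin gene CTSV (1.42 ± 0.14), the lipocalin gene LCN15 (1.38 ± 0.16), the proteoglycan gene BGN (1.32 ± 0.16) and the phospholipid transfer protein gene PLTP (1.26 ± 0.11). Large falls were those of the haptoglobin gene HP (-1.30 ± 0.34), VSNL1 (-1.28 ± 0.28), the glycerol-3-phosphate dehydrogenase gene GPD1 (-1.03 ± 0.18), ODAM (-1.005 ± 0.137), AGXT (-0.96 ± 0.19), TSPAN8 (-0.90 ± 0.21) and TKFC (-0.89 ± 0.14). The naming rule required that these genes separate the 3 treated from the 3 control arrays without overlap, so this is no result for them. Of all genes tested 27.6% did so, against 10% by chance.

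Of the 36 mitosis genes, 22 rose in the microsystem, 0 fell and 14 did not pass, and 31 rose when adjusted over the list alone. CEP55 rose by 0.98 ± 0.10, the centrosome kinase gene NEK2 by 0.96 ± 0.15, TTK by 0.87 ± 0.15 and the cyclin-dependent kinase gene CDK1 by 0.81 ± 0.16. Camera called the list at adjusted p = 1.23e-18, against an adjusted p = 0.646 with an estimated correlation. Of the 27 p53 targets, 13 rose, 0 fell and 14 did not pass, and 18 rose when adjusted over the list alone. TP53I3 rose by 1.08 ± 0.10, POLH by 0.92 ± 0.08, TP53INP1 by 0.75 ± 0.16 and DDB2 by 0.73 ± 0.08. The list passed at adjusted p = 6.95e-11 (adjusted p = 0.204 with an estimated correlation). Of the 40 DNA replication genes, 11 rose, 0 fell and 29 did not pass, and 20 rose when adjusted over the list alone. They included TK1 (0.77 ± 0.13), POLA2 (0.70 ± 0.12) and CDC45 (0.66 ± 0.12). The list passed at adjusted p = 1.88e-10 (adjusted p = 0.646 with an estimated correlation), and its mean fell from 0.37 to 0.205 without microsystem control 1. The actin and YAP target list passed at adjusted p = 0.0238, with 6 of 29 genes that rose, 0 that fell, 23 that did not pass and 8 that rose when adjusted over the list alone (adjusted p = 0.646 with an estimated correlation). Smooth muscle actin (ACTA2) rose by 0.56 ± 0.08, vinculin (VCL) by 0.49 ± 0.09 and the receptor kinase gene AXL by 0.60 ± 0.15. The list lost its call without microsystem control 2 or microsystem treated 3 (adjusted p = 0.186 and 0.167), and without the latter its mean fell from 0.205 to 0.12. Of 27 extracellular matrix genes, 7 rose, 1 fell and 19 did not pass, and 8 rose and 1 fell when adjusted over the list alone. Beside BGN, the protease inhibitor genes TIMP1 and TIMP2 rose by 1.01 ± 0.13 and 0.71 ± 0.11, while the collagen crosslinking enzyme gene LOX fell by 0.94 ± 0.26 with overlapping groups. The matrix list passed at adjusted p = 0.0491 (adjusted p = 0.646 with an estimated correlation) and not with the replicate block (adjusted p = 0.0656) or without any of 8 single arrays (adjusted p up to 0.232).

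Of 28 ribosomal protein genes, 2 fell in the microsystem, RPL22 by 0.34 ± 0.09 and RPS23 by 0.25 ± 0.07, while 0 rose and 26 did not pass, and 7 fell when adjusted over the list alone. The list passed at adjusted p = 3.74e-05 (adjusted p = 0.646 with an estimated correlation). Of 37 respiratory chain genes, CYC1 alone fell, by 0.33 ± 0.10, 0 rose and 36 did not pass, and 0 passed when adjusted over the list alone. This list passed at adjusted p = 0.0166 (adjusted p = 0.744 with an estimated correlation) and lost the call without microsystem control 2 or microsystem treated 2 (adjusted p = 0.232 and 0.0861), and without the former its mean went from -0.10 to -0.04. Of 18 hepatocyte transcription factor genes, HNF4G fell by 0.64 ± 0.07 and ESRRA by 0.33 ± 0.10, with 0 that rose, 16 that did not pass and the same number, 2, that fell when adjusted over the list alone. The list passed at adjusted p = 0.0491 (adjusted p = 0.646 with an estimated correlation), and not with the replicate block (adjusted p = 0.0521) or without any of 8 single arrays (adjusted p up to 0.425). Its mean of -0.12 was -0.08 without microsystem control 2 and -0.05 without microsystem treated 3. The cholesterol synthesis list shifted up at adjusted p = 0.0383 (adjusted p = 0.795 with an estimated correlation), with 0 of 18 genes that passed, over all genes or when adjusted over the list alone. DHCR7 came nearest at 0.26 ± 0.09 (adjusted p = 0.0894). It passed with the replicate block (adjusted p = 0.0488) and with the block within each culture (adjusted p = 0.0359), in a range of 0.0359 to 0.265 over its alternatives. The call was lost without microsystem control 3, microsystem treated 1 or microsystem treated 2 (adjusted p from 0.155 to 0.211), and the list mean of 0.14 was 0.09 without microsystem treated 1 and 0.23 without microsystem treated 3.

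HMOX1 rose in the microsystem by 0.58 ± 0.12 (adjusted p = 0.0086), CDKN1A by 0.52 ± 0.10 (adjusted p = 0.00968), MKI67 by 0.49 ± 0.11 (adjusted p = 0.0182) and CYP3A4, with the uncertainty given above and a control mean under the 40th percentile of its arrays, by 0.66 ± 0.19 (adjusted p = 0.0433). CYP1A1, CYP2E1 and GCLM differed by 0.10 ± 0.14, -0.02 ± 0.08 and 0.37 ± 0.12 (adjusted p = 0.681, 0.894 and 0.0738). GCLM passed with the replicate block (adjusted p = 0.0362) and with the block within each culture (adjusted p = 0.0151), in a range of 0.0151 to 0.227 over its alternatives. Both arrays numbered 3 stood apart on the third component, and without them 677 genes passed in place of 1196. Without microsystem control 2 or microsystem treated 2 alone, 605 and 460 genes passed. Of the 44 genes named by the fixed rule that passed, 15 lost the call without some single array, among them UCA1 (highest adjusted p = 0.0643), HP (0.118), VSNL1 (0.0641), TSPAN8 (0.0662), TP53INP1 (0.0592), AXL (0.0805), LOX (0.155), RPL22 (0.101), RPS23 (0.15), CYC1 (0.178), ESRRA (0.148), CYP3A4 (0.163), CDKN1A (0.0526) and MKI67 (0.0757).

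**Figure D2:**
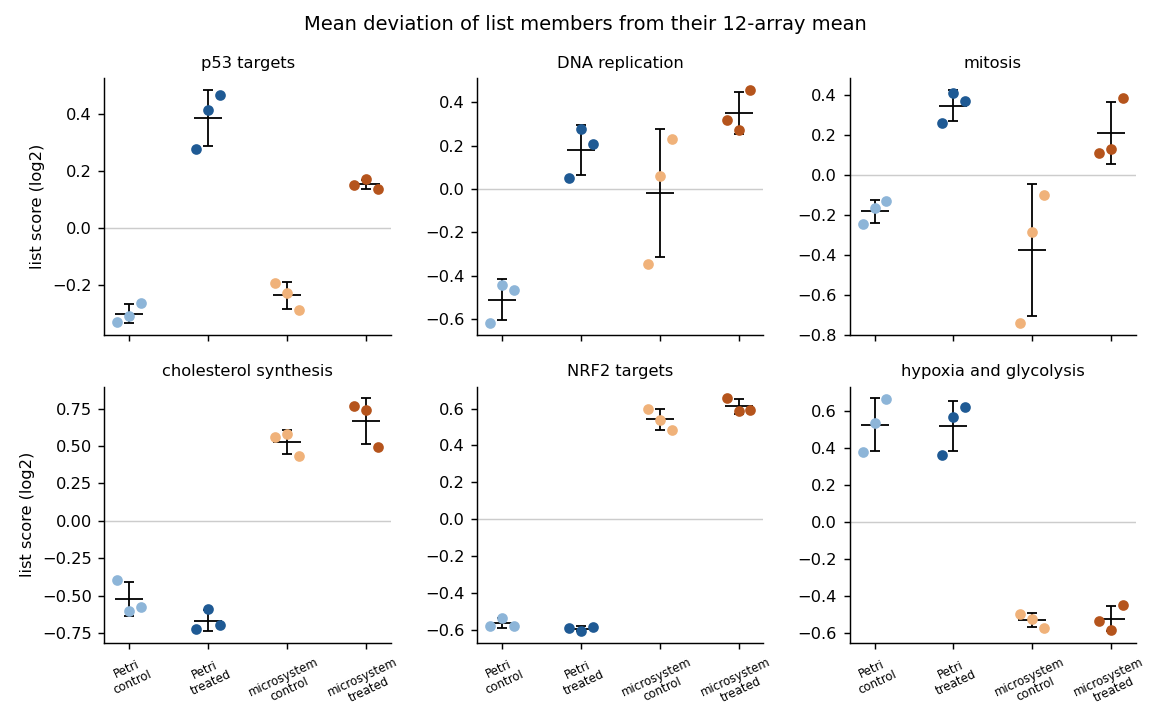
Mean deviation of the members of 6 gene lists from their own mean over the 12 arrays (log2), with 1 point per array and bars for the group mean and SD (n = 3). The mean p53, DNA replication and mitosis scores of treated groups lie above those of control groups in both cultures, and the mean NRF2 and cholesterol synthesis scores are higher, and the hypoxia and glycolysis scores lower, in the microsystem groups.

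The third question was whether treatment acted alike in the cultures. Across the 13199 genes, the treatment effects correlated with Pearson's r = 0.661 and Spearman's rho = 0.634, values across genes, which are not independent replicates. These effects share no arrays. In both cultures 483 genes rose and 68 fell, against 70.6 and 6.98 for independent lists of the same lengths, and opposite calls were made for 0 and 1 genes, against 29.6 and 16.7. That 1 gene was HMOX1, whose mean fell from 8.70 to 8.27 in Petri dishes and rose from 9.67 to 10.25 in the microsystem. Its Petri call was lost without any of 6 single arrays (limma, adjusted p from 0.0574 to 0.111), and its difference of treatment effects did not pass. Among the 2011 genes called in either culture, 93.2% had the same sign in both. The test of the difference itself passed for 4 genes. Of the 13199 genes, 970 had an unadjusted p under 0.05, which a share of 0.05 would have with no difference at all. CEL rose less in the microsystem, from 5.92 ± 0.19 to 6.69 ± 0.28 (SD, n = 3), a difference of treatment effects of -1.65 ± 0.19 (adjusted p = 0.00762). LAPTM5 (probe set 7914270), a lysosomal membrane protein gene with a Petri control mean under the 40th percentile of its arrays, rose by 1.26 ± 0.13 in Petri dishes against 0.01 ± 0.13 in the microsystem (difference -1.25 ± 0.18, adjusted p = 0.0369). HSPA4L (probe set 8097335), a chaperone gene, rose by 0.95 ± 0.08 in Petri dishes against 0.16 ± 0.08 (difference -0.79 ± 0.12, adjusted p = 0.0369). The angiotensin receptor gene AGTR1 (probe set 8083240) fell by 0.70 ± 0.09 in Petri dishes, with a change of 0.15 ± 0.09 in the microsystem that did not pass (difference 0.84 ± 0.12, adjusted p = 0.0369). Without some single arrays the calls of AGTR1, LAPTM5 and HSPA4L were lost, with adjusted p up to 0.167 in each. Only 1 gene passed without microsystem control 2, microsystem treated 1, Petri control 2, Petri control 3 or Petri treated 2, and 2 passed without Petri treated 1 or 3, while 12 and 13 passed without microsystem control 1 and 3. With the replicate block within each culture 24 genes passed.

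For 8 lists the mean treatment effect differed between cultures with the preset correlation, and for none of the 34 with an estimated correlation or by fry. No member passed over all genes in any of these 8 lists. The p53 targets (mean difference -0.30, adjusted p = 4.94e-10, adjusted p = 0.26 with an estimated correlation) and the DNA replication genes (-0.32, adjusted p = 4.94e-10, adjusted p = 0.771 with an estimated correlation) had the smaller effect in the microsystem. Adjusted over the list alone, 8 of 27 p53 targets and 0 of 40 DNA replication genes passed. An exact permutation of treatment labels within each culture gave p = 0.475 and 0.44 for the difference of these list scores. Both were 0.915 when adjusted over 34 lists. Arrangements that reverse the labels of 1 culture turn the shared treatment effect into a difference, so this test has little power here. TP53I3 came nearest in the first list at -0.79 ± 0.14 (adjusted p = 0.0776) and RFC2 in the second at -0.57 ± 0.18 (adjusted p = 0.445). With the preset correlation, the cholesterol synthesis list shifted down in Petri dishes and up in the microsystem. Neither of these calls held with an estimated correlation, and 0 of 18 genes passed in the microsystem. The mean difference of this list was 0.29 (adjusted p = 4.94e-10, adjusted p = 0.381 with an estimated correlation), with MSMO1 at 0.63 ± 0.11 (adjusted p = 0.0776) and 6 of 18 genes when adjusted over the list alone. Higher treatment effects in the microsystem also passed for extracellular matrix genes (0.13, adjusted p = 0.00276, adjusted p = 0.381 with an estimated correlation) and ATF4 response genes (0.16, adjusted p = 0.0134, adjusted p = 0.786 with an estimated correlation). The same held for immediate early genes (0.18, adjusted p = 0.0174, adjusted p = 0.451 with an estimated correlation) and drug transporters (0.14, adjusted p = 0.0194, adjusted p = 0.278 with an estimated correlation). It held as well for fatty acid synthesis genes (0.13, adjusted p = 0.0312, adjusted p = 0.786 with an estimated correlation). Adjusted over the list alone, 0 of 27 matrix, 1 of 29 ATF4 response, 1 of 23 immediate early, 0 of 14 transporter and 0 of 19 fatty acid synthesis genes passed. The members nearest to passing were CTSB at 0.39 ± 0.13 (adjusted p = 0.445), SLC7A11 at 1.44 ± 0.35 (adjusted p = 0.262), JUNB at 0.89 ± 0.15 (adjusted p = 0.059), ABCC3 at 0.34 ± 0.12 (adjusted p = 0.549) and PNPLA3 at 0.71 ± 0.23 (adjusted p = 0.445). JUNB passed with the replicate block (adjusted p = 0.038, range over its alternatives 0.00999 to 0.225) and TP53I3 with the block within each culture (adjusted p = 0.0395, range 0.00999 to 0.253). Single arrays ended the calls of the ATF4 (3 arrays, adjusted p up to 0.576), immediate early (2, up to 0.229), transporter (4, up to 0.108) and fatty acid synthesis lists (5, up to 0.185). Without microsystem treated 3 the immediate early mean was 0.07, the matrix mean 0.08 and the fatty acid synthesis mean 0.20. The ATF4 mean was 0.04 without Petri control 2, 0.09 without Petri treated 1 and 0.29 without Petri control 1, and the DNA replication mean was -0.49 and -0.20 without microsystem control 1 and 3.

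**Figure D3:**
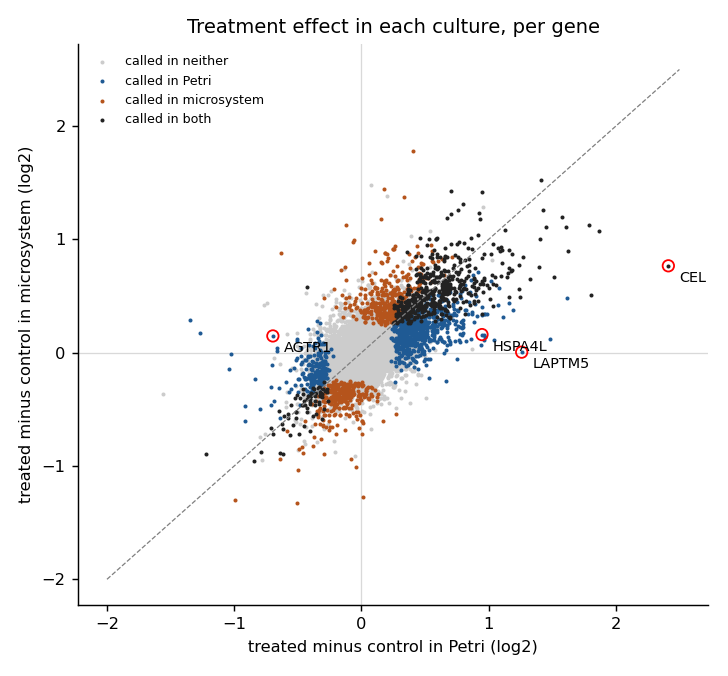
Treatment effect of each of the 13199 genes in Petri dishes (x axis, log2) against that in the microsystem (y axis, log2), with the line of equal effects dashed and genes coloured by the culture in which they passed the test. Most genes called in both lie in the quadrant of rises (483 genes), and the 4 circled genes are those whose difference between cultures passed.

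The fourth comparison set untreated cells of the microsystem against untreated cells in Petri dishes. The lists of NRF2 target, conjugation, sterol synthesis and fatty acid synthesis genes shifted up in the microsystem, and those of hypoxia and glycolysis, matrix, actin and acute phase genes shifted down. Of these calls, that of NRF2 targets alone held with an estimated correlation. CYP1A1 (probe set 7990391), the classic target of the aryl hydrocarbon receptor, was higher by 5.86 ± 0.14 (5.36 ± 0.22 in Petri dishes and 11.21 ± 0.06 in the microsystem, SD, n = 3), a 57.9-fold difference (adjusted p = 1.18e-11). AKR1B10 (probe set 8136336), an aldo-keto reductase gene induced by NRF2, was 43.4-fold higher (5.44 ± 0.25, adjusted p = 1.72e-08). The hexokinase gene HK2 (probe set 8042942) was lower by -2.55 ± 0.17 (12.00 ± 0.16 against 9.45 ± 0.26, SD, n = 3, adjusted p = 2.26e-07). In all, 3504 genes rose and 2422 fell in the microsystem relative to Petri dishes, 44.9% of those tested, and of the 2236 with at least a 1.5-fold difference 1378 rose. Non-overlapping groups were seen for 52.4% of genes, against 10% by chance. They were also seen for every gene named as different in this comparison, as the naming rule required of the largest rises and falls. Large rises were also those of the betaine transporter gene SLC6A12 (3.17 ± 0.63), ARRDC4 (2.92 ± 0.13), the hyaluronan receptor gene LYVE1, a marker of lymphatic endothelium (2.67 ± 0.41, from a Petri mean under the 40th percentile of its arrays), the aldehyde dehydrogenase gene ALDH3A1 (2.61 ± 0.31), the transcription factor gene EGR1 (2.58 ± 0.21) and SGK2 (2.505 ± 0.20). Large falls were also those of the YAP target ANKRD1 (-3.42 ± 0.48), CHST15 (-3.10 ± 0.14), the focal adhesion gene TNS1 (-2.99 ± 0.18), LCN15 (-2.96 ± 0.16), PFKFB3 (-2.52 ± 0.21), NDRG1 (-2.47 ± 0.17) and LOXL3 (-2.44 ± 0.14).

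Of 21 NRF2 target genes, 19 rose, 0 fell and 2 did not pass, with 20 that rose when adjusted over the list alone. Beside AKR1B10, the epoxide hydrolase gene EPHX1 rose by 2.08 ± 0.20, GCLM by 1.92 ± 0.12 and the quinone reductase gene NQO1 by 1.48 ± 0.12. The list passed at adjusted p = 1.83e-10 and held with an estimated correlation (adjusted p = 0.00263), the only list of this comparison to do so. HMOX1 rose by 0.97 ± 0.12 (adjusted p = 2.13e-05). Of 6 AHR targets, CYP1A1, ALDH3A1 and NQO1 rose, NFE2L2 fell by 0.59 ± 0.09 and 2 did not pass, with the same counts of 3 and 1 when adjusted over the list alone (adjusted p = 0.0262, adjusted p = 0.217 with an estimated correlation). Of 16 conjugation enzyme genes, 11 rose, 0 fell and 5 did not pass, also when adjusted over the list alone (adjusted p = 0.00212, adjusted p = 0.217 with an estimated correlation). The glutathione transferase gene MGST1 rose by 1.91 ± 0.11, TPMT by 1.16 ± 0.12, UGT2B7, uncertain because of near-identical relatives and whose Petri mean lay under the 40th percentile of its arrays, by 0.88 ± 0.13 and SULT2A1 by 0.85 ± 0.19. The lists of cytochrome P450 and phase I genes (7 rose, 3 fell and 4 did not pass, also when adjusted over the list alone, adjusted p = 0.0678) and of drug transporters (6 rose, 3 fell and 5 did not pass, also when adjusted over the list alone, adjusted p = 0.468) did not pass. CYP3A4 was higher by 1.79 ± 0.19 (adjusted p = 7.35e-06), a difference between means of 2.89 and 4.68 that lay under the 25th and the 40th percentile of their arrays and so is no measure of fold. CYP2E1 fell by 0.24 ± 0.08 (adjusted p = 0.0285). Of 18 cholesterol synthesis genes, 16 rose, 0 fell and 2 did not pass, with 17 when adjusted over the list alone (adjusted p = 1.04e-10, adjusted p = 0.217 with an estimated correlation). ACAT2 rose by 1.85 ± 0.11, HMGCS1 by 1.45 ± 0.11, NSDHL by 1.44 ± 0.10 and the mevalonate kinase gene MVK by 1.40 ± 0.12. Of 19 fatty acid synthesis genes, 14 rose, 0 fell and 5 did not pass, also when adjusted over the list alone (adjusted p = 0.000123, adjusted p = 0.217 with an estimated correlation). They included GPAM (1.87 ± 0.20), FADS2 (1.34 ± 0.14), the fatty acid synthase gene FASN (1.19 ± 0.15) and PNPLA3 (1.17 ± 0.16). Of 20 fatty acid oxidation genes, 13 rose, 3 fell and 4 did not pass, with 13 and 5 when adjusted over the list alone (adjusted p = 0.0356, adjusted p = 0.355 with an estimated correlation). ETFDH, EHHADH and the carnitine carrier gene SLC25A20 rose by 1.503 ± 0.13, 1.251 ± 0.17 and 1.04 ± 0.13, while ANGPTL4, a lipase inhibitor, fell by 2.12 ± 0.15.

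Of 30 hypoxia and glycolysis genes, 0 rose, 27 fell and 3 did not pass, also when adjusted over the list alone (adjusted p = 4.38e-14, adjusted p = 0.199 with an estimated correlation). HK2 and PFKFB3 of glycolysis fell with NDRG1 and with the angiogenic factor gene VEGFA (-2.21 ± 0.14). Of 11 glycolytic enzyme genes, HK2 among them, 8 fell, with a median of -0.285. The other 19 members, PFKFB3 among them, all fell, with a median of -1.23. Of 29 actin and YAP target genes, 2 rose, 15 fell and 12 did not pass, with 2 and 16 when adjusted over the list alone (adjusted p = 0.000224, adjusted p = 0.217 with an estimated correlation). Beside ANKRD1, the matricellular genes CCN2 and CCN1 fell by 1.67 ± 0.22 and 1.58 ± 0.34 and AXL by 1.56 ± 0.15. Of 27 extracellular matrix genes, 0 rose, 12 fell and 15 did not pass, with 14 that fell when adjusted over the list alone (adjusted p = 4.4e-05, adjusted p = 0.199 with an estimated correlation). LOX fell by 1.70 ± 0.26, the perlecan gene HSPG2 by 1.12 ± 0.11 and the agrin gene AGRN by 0.64 ± 0.10. Of 20 epithelial junction genes, 1 rose, 7 fell and 12 did not pass, also when adjusted over the list alone (adjusted p = 0.00781, adjusted p = 0.217 with an estimated correlation), with E-cadherin (CDH1) at -1.12 ± 0.21, CLDN1 at -0.84 ± 0.18, DSP at -0.82 ± 0.09 and KRT19 at -0.74 ± 0.13. Of 16 acute phase and NF-kB genes, 0 rose, 8 fell and 8 did not pass, also when adjusted over the list alone (adjusted p = 0.00212, adjusted p = 0.281 with an estimated correlation). The hepcidin gene HAMP fell by 2.13 ± 0.17, the chemokine gene CCL20 by 1.10 ± 0.25, the uncertain ORM1 by 0.89 ± 0.24 and TNFAIP3 by 0.84 ± 0.15. Of 36 plasma protein genes, 3 rose, 19 fell and 14 did not pass, with 4 and 19 when adjusted over the list alone (adjusted p = 0.000123, adjusted p = 0.355 with an estimated correlation). Complement C5 fell by 2.11 ± 0.28, ceruloplasmin (CP) by 1.39 ± 0.17, VTN by 1.22 ± 0.11 and the fibrinogen gene FGA by 1.12 ± 0.28, while ALB rose by 0.28 ± 0.08 (adjusted p = 0.0129) and AFP by 0.49 ± 0.13 (adjusted p = 0.00815).

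Of 40 DNA replication genes, 25 rose, 2 fell and 13 did not pass, with 26 and 2 when adjusted over the list alone (adjusted p = 4.59e-05, adjusted p = 0.513 with an estimated correlation). CDC6 rose by 1.63 ± 0.19, CDC7 by 1.59 ± 0.14 and GINS1 by 1.07 ± 0.18. Of 36 mitosis genes, 2 rose, 9 fell and 25 did not pass, also when adjusted over the list alone (adjusted p = 0.0234, adjusted p = 0.69 with an estimated correlation), with TTK at -0.72 ± 0.15 and CDK1 at -0.70 ± 0.16. This call was lost without microsystem control 1 (adjusted p = 0.447), where the mean went from -0.20 to -0.01, and the mean was -0.335 without microsystem control 3. MKI67 differed by 0.11 ± 0.11 (adjusted p = 0.461), and CDKN1A rose by 0.59 ± 0.10 (adjusted p = 0.000502). Of 18 heat shock protein genes, 11 rose, 0 fell and 7 did not pass, also when adjusted over the list alone (adjusted p = 0.00119, adjusted p = 0.217 with an estimated correlation), led by DNAJA1 (0.79 ± 0.09), DNAJB4 (0.73 ± 0.09) and HSPH1 (0.72 ± 0.10). Of 21 ER chaperone genes, 12 rose, 2 fell and 7 did not pass, also when adjusted over the list alone (adjusted p = 0.0262, adjusted p = 0.41 with an estimated correlation). SDF2L1 rose by 0.78 ± 0.10, MANF by 0.76 ± 0.09 and BiP (HSPA5) by 0.59 ± 0.09. The list lost its call without microsystem control 3 (adjusted p = 0.0542). Of 28 ribosomal protein genes, 0 rose, 9 fell and 19 did not pass, also when adjusted over the list alone (adjusted p = 0.00109, adjusted p = 0.41 with an estimated correlation), with RPL10A at -0.30 ± 0.09 and RPS25 at -0.29 ± 0.08, while RPL13 at -0.33 ± 0.09 had other probe sets at 0.14 and 0.57. Of 18 hepatocyte transcription factor genes, 1 rose, 8 fell and 9 did not pass, also when adjusted over the list alone (adjusted p = 0.0262, adjusted p = 0.409 with an estimated correlation). The aryl hydrocarbon receptor gene AHR fell by 0.99 ± 0.09, FOXA2 by 0.89 ± 0.13 and HLF by 0.72 ± 0.09. The 1 gene that rose was CEBPA, at 0.37 after quantile normalization, where its call was lost (limma, adjusted p = 0.0617). Its call was also lost without any of 3 single arrays (adjusted p up to 0.142). The call of the list was lost without microsystem control 3 (adjusted p = 0.0608). Of 8 leukocyte and erythroid markers, 1 rose, 4 fell and 3 did not pass, also when adjusted over the list alone (adjusted p = 0.044, adjusted p = 0.217 with an estimated correlation). The macrophage marker CD68 fell by 1.05 ± 0.09, NKG7 by 0.64 ± 0.13 and CD14 by 0.43 ± 0.12. This call was lost after quantile normalization (adjusted p = 0.0693) and without microsystem control 2 or Petri control 3 (adjusted p up to 0.104). The lists of fibroblast and stellate, endothelial, and cholangiocyte and progenitor markers did not pass (adjusted p = 0.686, 0.0678 and 0.389). The calls of ALB and CYP2E1 were lost without some single arrays (adjusted p up to 0.0534 and 0.126).

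**Figure D4:**
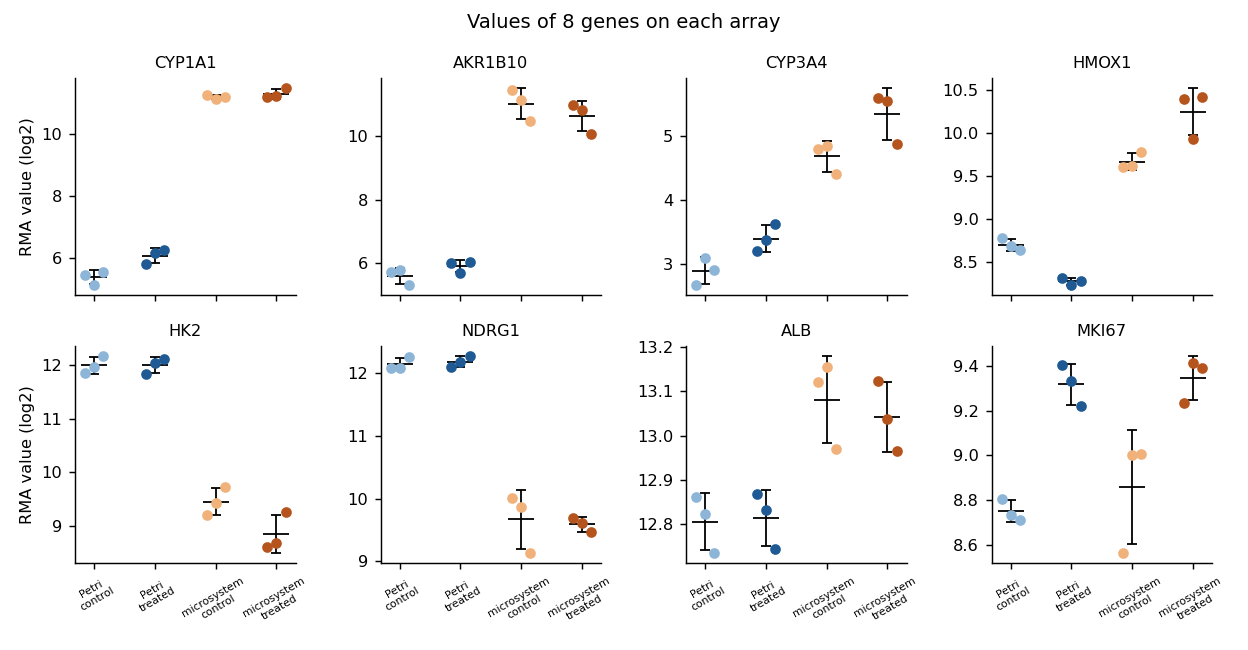
Deposited log2 values of 8 genes on each of the 12 arrays, with bars for the group mean and SD (n = 3) and an axis of its own for each gene, not starting at 0. CYP1A1 and AKR1B10 stand above 10 on every microsystem array and below 7 on every Petri array, and HK2 and NDRG1 are lower on every microsystem array than on any Petri array.

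The fifth comparison repeated this contrast in treated cells. It gave 2977 genes that rose and 2490 that fell in the microsystem relative to Petri dishes, with 1117 and 841 at 1.5-fold or more. Of the genes called with or without treatment, 4385 were called in both, 4378 of them in the same direction, and the culture effects correlated across genes with r = 0.912. CYP1A1 was higher by 5.25 ± 0.14 (adjusted p = 4.98e-11), AKR1B10 by 4.73 ± 0.25, SLC6A12 by 3.70 ± 0.63 and the olfactory receptor gene OR2B6 by 3.15 ± 0.56, the last from a Petri mean under the 25th percentile of its arrays and so no measure of fold. HK2 was lower at -3.15 ± 0.17 (adjusted p = 4.47e-08), TNS1 at -3.07 ± 0.18, CHST15 at -2.91 ± 0.14 and SERPINA11 at -2.77 ± 0.12. Groups did not overlap for 52.9% of genes, against 10% by chance. Of the 34 lists, 17 passed, and the NRF2 list alone held with an estimated correlation (19 of 21 genes rose, 2 did not pass and 19 rose when adjusted over the list alone, adjusted p = 4.71e-13, adjusted p = 0.00115 with an estimated correlation). Its members SLC7A11, GCLM and HMOX1 rose by 2.83 ± 0.25, 2.08 ± 0.12 and 1.98 ± 0.12. Cholesterol synthesis genes rose in 17 of 18 cases, over all genes and when adjusted over the list alone (adjusted p = 9.93e-15, adjusted p = 0.2 with an estimated correlation), with ACAT2 at 2.07 ± 0.11 and HMGCS1 at 1.97 ± 0.11. Of 30 hypoxia and glycolysis genes, 26 fell, 1 rose and 3 did not pass, with 27 and 1 when adjusted over the list alone (adjusted p = 1.34e-13, adjusted p = 0.2 with an estimated correlation), among them NDRG1 (-2.59 ± 0.17) and PFKFB3 (-2.001 ± 0.21). Fatty acid synthesis genes rose in 14 of 19 cases with 1 fall, also when adjusted over the list alone (adjusted p = 2.61e-06, adjusted p = 0.2 with an estimated correlation), with GPAM at 2.23 ± 0.20 and PNPLA3 at 1.88 ± 0.16. Ribosomal protein genes fell in 19 of 28 cases, and in 20 when adjusted over the list alone (adjusted p = 2.31e-05, adjusted p = 0.312 with an estimated correlation), with RPL10A at -0.46 ± 0.09. Of 14 cytochrome P450 and phase I genes, 7 rose, 2 fell and 5 did not pass, also when adjusted over the list alone (adjusted p = 0.0347, adjusted p = 0.2 with an estimated correlation), with EPHX1 at 1.74 ± 0.20 and the uncertain CYP3A5 and CYP3A4 at 2.84 ± 0.30 and 1.94 ± 0.19, the latter from a Petri mean under the 25th percentile of its arrays and no measure of fold.

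Of the 27 p53 targets, 7 were higher in treated microsystem cells than in treated Petri cells, 15 were lower and 5 did not pass, with 7 and 16 when adjusted over the list alone (adjusted p = 0.0132, adjusted p = 0.334 with an estimated correlation). PLK2, AEN and PPM1D were lower at -0.94 ± 0.18, -0.87 ± 0.10 and -0.86 ± 0.12, and TIGAR was higher by 0.89 ± 0.10. The other lists that passed kept the direction they had in controls. Actin and YAP targets had 1 rise and 15 falls among 29 (adjusted p = 0.000934, adjusted p = 0.304 with an estimated correlation), with FHL2 at -1.53 ± 0.09. Matrix genes had 1 and 10 among 27 (adjusted p = 0.00689, adjusted p = 0.304 with an estimated correlation), with LOX at -2.56 ± 0.26. Plasma proteins had 3 and 17 among 36 (adjusted p = 0.00286, adjusted p = 0.427 with an estimated correlation), with AHSG at -1.46 ± 0.07. Acute phase genes had 0 and 7 among 16 (adjusted p = 0.0124, adjusted p = 0.334 with an estimated correlation), with HAMP at -1.09 ± 0.17. Junction genes had 2 and 10 among 20 (adjusted p = 0.0132, adjusted p = 0.304 with an estimated correlation), with PKP4 at -0.69 ± 0.07. Hepatocyte transcription factors had 2 and 8 among 18 (adjusted p = 0.0151, adjusted p = 0.334 with an estimated correlation), a call lost without microsystem treated 3 (adjusted p = 0.0864). AHR targets had 4 and 1 among 6 (adjusted p = 0.00566, adjusted p = 0.188 with an estimated correlation), with ALDH3A1 at 2.69 ± 0.31. Conjugation enzymes had 9 and 1 among 16 (adjusted p = 0.00689, adjusted p = 0.304 with an estimated correlation), with MGST1 at 1.98 ± 0.11. Heat shock proteins had 10 and 1 among 18 (adjusted p = 0.00689, adjusted p = 0.312 with an estimated correlation), with DNAJB4 at 1.04 ± 0.09. Fatty acid oxidation genes had 12 and 3 among 20 (adjusted p = 0.0132, adjusted p = 0.309 with an estimated correlation), with ACOT1, uncertain because of its near-identical relative ACOT2, at 1.11 ± 0.10. Rises and falls when adjusted over the list alone were 1 and 15 for actin and YAP targets, 1 and 10 for matrix, 6 and 19 for plasma proteins, 0 and 7 for acute phase, 2 and 10 for junctions, 2 and 10 for transcription factors, 5 and 1 for AHR targets, 9 and 1 for conjugation, 12 and 2 for heat shock and 12 and 4 for fatty acid oxidation.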

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

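The tests of array scaling, of whole-list drift and of RNA from other cell types were chosen after the results they bear on were seen, and the counts of other splits and the test of oxygen-regulated genes were written beforehand. A test of the difference between the treatment effects in the cultures singled out 4 genes, AGTR1 (0.84), CEL (-1.65), HSPA4L (-0.79) and LAPTM5 (-1.25), as log2 differences, microsystem minus Petri. It also singled out 8 lists by their mean log2 difference: drug transporters (0.14), cholesterol synthesis (0.29), fatty acid synthesis (0.13), p53 targets (-0.30), DNA replication (-0.32), ATF4 amino acid response (0.16), extracellular matrix (0.13) and immediate early genes (0.18). None of the 8 list calls held with an estimated correlation. Probe sets without a gene name here were outside the report's comparisons, and of the 5539 tested some rose above the other group: 6 with treatment in Petri dishes, 2 with treatment in the microsystem, 370 with culture in controls and 353 with culture in treated cells. In the culture comparisons 310 and 346 of them fell. For the difference of treatment effects limma called 0 of the 5539. An unadjusted p under 0.05 was seen for 219, and a share of 0.05 would have it with no difference at all.

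The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. Every split but the real one mixes both true groups, so the real effect widens the spread within its groups. The low counts of these splits therefore do not measure chance. For treatment in Petri dishes 1 of the 10, the real split, called as many genes (1367, highest other 0), and among the 4 splits that part all 3 replicate numbers the highest other count was also 0. For treatment in the microsystem it was 1 of 10 (1196, highest other 20), for culture in controls 1 of 10 (5926, highest other 0) and for culture in treated cells 1 of 10 (5467, highest other 0). For the difference of treatment effects, 9 of 100 splits of the treatment labels within cultures, the real one included, called at least its 4 genes, so chance was not excluded for that count. The highest other split called 470 genes. The 5 highest, with 50 to 470 genes, reverse all or most of the treatment labels in 1 culture and keep all or most in the other. This turns the shared treatment effect into a difference, a structure of the samples, so the count does not measure chance alone. The other 3 called 5, 7 and 15 genes.

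The DNA replication, mitosis and p53 target lists shifted up with treatment in both cultures with the preset correlation, and of these calls that of p53 targets in Petri dishes alone held with an estimated correlation (adjusted p = 0.028). The lowest of the 6 list means, that of DNA replication in the microsystem, was 0.365 (log2) after quantile normalization. The array medians already lay between 5.556 and 5.629, so this step could change a list mean little and hardly tests array scaling. The mean of the deposited values fell from 0.37 to 0.205 without microsystem control 1. For a drift of whole lists between replicate arrays, the gap between the lowest treated and the highest control list score was examined. It was at least 2.23 times the wider within-group range for p53 targets in both cultures and for DNA replication and mitosis in Petri dishes. For DNA replication and mitosis in the microsystem it was 0.0677 and 0.326 times that range. This division of the lists follows the size of the gaps, so the larger gaps alone do not decide. Over all 6 gaps the smallest was 0.0677, so drift and treatment cannot be told apart for the pattern as a whole. Over both cultures each list score reached an exact permutation p of 0.005 (0.0213 when adjusted over 34 lists). With Petri labels exchanged within same-numbered pairs alone it was 0.0125 (0.0531 when adjusted). These are the smallest that 400 and 160 arrangements can give. The scores of heat shock proteins, extracellular matrix, apoptosis and ribosomal proteins reached them too. So did that of endothelial markers, with a mean rise of 0.24. The last list held only 4 genes, with mean control levels of 5.46 in Petri dishes and 5.07 in the microsystem, under the array medians. A response to acetaminophen may underlie the shift, as a hypothesis. A shared handling difference between treated and control cultures stays open. So does RNA of other cells, although all samples are described as HepG2C3A cells.

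Hypoxia genes were lower and NRF2 target genes higher in the microsystem, and with an estimated correlation the NRF2 call held (adjusted p = 0.00263) and the hypoxia call was lost (adjusted p = 0.199). The smaller of the absolute list means was 1.07 (log2) after quantile normalization. The array medians already lay between 5.556 and 5.629, so this step could change a list mean little and hardly tests array scaling. All samples are described as HepG2C3A cells, a cell line, and the markers alone leave RNA of other cells open in both cultures. The highest mean difference of 3 marker lists, -0.033 ± 0.063 (SE over members) for 6 fibroblast and stellate markers, lay within its error of 0. The 4 endothelial markers stood at -0.40 ± 0.12 and the 8 leukocyte and erythroid markers at -0.32 ± 0.15, lower in the microsystem. LYVE1, a marker of lymphatic endothelium outside the lists, was higher by 2.67 in microsystem controls (4.57 ± 0.22 against 7.24 ± 1.11, SD, n = 3). A rise of this 1 gene does not show that such cells were present. Of 32 HIF target genes outside the list, 78.1% fell in controls (25 fell, 0 rose), against 18.3% of all genes. A different oxygen supply in the microsystem would predict such a fall. These genes were measured on the same arrays as the hypoxia list, and some, such as LOX and ANGPTL4, are members of other lists. They are therefore not independent support. The labels give no oxygen measure, and other differences between the cultures, such as glucose supply, cell density or cell types, stay open as untested.

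The cholesterol synthesis list shifted down with treatment in Petri dishes and up in the microsystem with the preset correlation. Neither call held with an estimated correlation (adjusted p = 0.845 and 0.795), and 0 of 18 genes passed in the microsystem. The list mean of the difference was 0.35 (log2) after quantile normalization. The array medians already lay between 5.556 and 5.629, so this step could change a list mean little and hardly tests array scaling. An exact permutation test of the list score gave p = 0.04, and 0.68 when adjusted over 34 lists (0.075 and 0.595 with Petri labels exchanged within pairs), so a drift of the whole list between replicate arrays and a difference between the cultures cannot be told apart with 3 arrays per group.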

How the results depend on the processing

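The block within each culture and leaving out both microsystem arrays numbered 3 were chosen after the results were seen. Treatment in Petri dishes called 3602 genes with array weights, 392 at 1.5-fold and 2180 with the block within each culture. Treatment in the microsystem called 446 with only the arrays compared, 310 at 1.5-fold, 2109 with the block within each culture and 677 without both arrays numbered 3. At 1.5-fold the culture comparisons called 2236 in controls and 1958 in treated cells. The difference of treatment effects called 18 genes with the replicate block, 7 after quantile normalization, 10 with an intensity trend, 54 with array weights, 24 with the block within each culture and 11 without both arrays numbered 3. Leaving out 1 array gave 701 to 1520 genes in Petri dishes, 460 to 1440 in the microsystem, 4902 to 6029 for culture in controls, 4404 to 5653 in treated cells, 1 to 13 for the difference, and a correlation of treatment effects of 0.598 (without microsystem control 1) to 0.674. CYP51A1 in Petri dishes reversed to 0.15 and RPL13 in culture in controls to 0.13 with the mean of a gene's probe sets, whose members disagree. The other reversals were of genes that did not pass: ALB in Petri dishes (-0.009 with array weights, -0.027 without Petri control 3, -0.017 without Petri treated 1, highest 0.044 without Petri treated 3), AFP in Petri dishes (0.011 after quantile normalization, 0.039 with medians equal, 0.013 with array weights, 0.136 without Petri control 1, 0.046 and 0.053 without Petri treated 2 and 3, lowest -0.106 without Petri treated 1) and CYP2E1 in the microsystem (0.017 after quantile normalization, 0.007 with medians equal, 0.003 without microsystem control 3, 0.016 without microsystem treated 1, lowest -0.052 without microsystem treated 2). A fold minimum lowers counts by construction. For the rest the cause was not tested. Of 61 list calls, 58 were lost with an estimated correlation, 19 by fry, 6 without both microsystem arrays numbered 3, 3 after quantile normalization and 2 with the replicate block. Of 271 named gene results, 268 kept both their direction and their side of the threshold with the replicate block, 262 after quantile normalization and 263 without the filter. With only the arrays compared 241 kept both and 17 lost the call, and over all fits that left out 1 array gene results kept both 3049 times and lost the call 191 times, and list calls were kept 677 times and lost 55 times. Without both microsystem arrays numbered 3, 9 gene results lost the call. The alternative without cross-hybridizing probe sets was not run, since no probe set name marks them, and the difference has no version with only the arrays compared.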

Other observations

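The groups of genes given here were chosen after their values were seen, and none of their calls held with an estimated correlation. In controls, 33 of 49 histone genes rose in the microsystem relative to Petri dishes and 0 fell (median 0.50, adjusted p = 3.9e-06, adjusted p = 0.283 with an estimated correlation), and many of them are near-identical copies and uncertain for that reason. Of 35 proteasome subunit genes 24 rose and 0 fell (median 0.34, adjusted p = 8.25e-06, adjusted p = 0.355 with an estimated correlation), and of 18 vacuolar ATPase subunit genes 11 rose and 0 fell (median 0.34, adjusted p = 0.000528, adjusted p = 0.283 with an estimated correlation). With treatment in the microsystem, 12 of 72 mitochondrial ribosomal protein genes fell, 5 with array medians set equal, and 0 rose (median -0.17, adjusted p = 2.15e-09, adjusted p = 0.231 with an estimated correlation), and 14 of 82 C/D box small nucleolar RNAs fell and 0 rose (median -0.29, adjusted p = 7.67e-11, adjusted p = 0.211 with an estimated correlation).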
